A study of Rattus norvegicus with 12 samples.

How the data were processed

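Gene expression was measured in rat kidney on Affymetrix 3' expression arrays. Per the series design, both kidneys of 6 animals of each of 4 strains (SD, PCK, FHH and FHH.Pkhd1) were taken at 30 days of age and stored in RNAlater, RNA was extracted with Trizol, and the RNA of each strain was pooled and hybridized to 3 arrays. Biotin-labelled cRNA was prepared with the 3' IVT Express kit, per the labels' protocols. The 12 arrays form 4 groups of 3 technical replicates, and the group of each array was taken from its strain label.

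The deposited values were log2 probe set signals. They were made with RMA and Partek 6.2, per the submitters' processing notes, which give no order of steps. Whether the 12 arrays were normalized together is not given in the sources used here. The values ran from 2.38 to 14.41, with array medians of 6.41 to 6.46, and they were used as deposited with no further normalization.

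The table held 31099 probe sets, of which 57 were control probe sets and were left out of the tests. Of the other 31042, 20826 carried a single gene symbol, 436 carried several and 9780 none. Symbols were matched to current gene records of the GRCr8 assembly, used for names, chromosome and gene order alone, and 20758 probe sets matched. For each of the resulting 14217 genes the probe set with the highest mean over all arrays was kept. A gene was tested when its highest group mean reached the 40th percentile of all values, 5.74, taken as the detection level, which left 10895 genes. No probe set carried the symbol Pkhd1.

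Differences were estimated with limma 3.58.1 in R 4.3.3 in a fit of all 12 arrays with 1 mean per strain. The contrasts were PCK minus SD, FHH.Pkhd1 minus FHH, PCK minus FHH.Pkhd1, SD minus FHH, and the interaction, which is the first minus the second. Variances were moderated by eBayes (prior degrees of freedom 4.01, residual degrees of freedom 8). P-values were adjusted by Benjamini and Hochberg over all genes tested in a comparison. A gene was called when its adjusted p was under 0.05 and its difference was at least 1.5-fold. The replicates are arrays of 1 pool, so the test compares pools and not strains of animals.

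Gene lists for injury, immune, signalling and metabolic functions and for cell types of the kidney and neighbouring tissues were written before the data were examined, as were the comparisons, thresholds, named-gene rule and alternatives. A list was described by the percentile of its median log2 difference among 10000 random lists of the same size, matched on mean expression in 20 bins. It was said to lie apart below the 2.5th or above the 97.5th percentile. Of 34 lists, 31 had enough measured genes for a percentile. Camera, with a preset correlation of 0.01 and with an estimated one, and fry were run as alternatives, each adjusted over the lists of a comparison.

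The named genes were, per comparison, the 10 largest differences higher and the 10 lower among called genes whose arrays did not overlap between groups and whose symbol is no placeholder. To these were added up to 4 called members of each list (the 2 largest values where none was called), the 10 largest of the genes called the same way in both Pkhd1 comparisons, and the 5 largest on a chromosome of interest. Overlap of calls and the share of called genes per chromosome were tested with two-sided Fisher's exact tests across genes, adjusted over the 4 directions and over 110 chromosome tests. Control probe sets were compared with two-sided exact permutation tests of 3 arrays against 3.

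The procedure was tested on simulated data for PCK minus SD with 10895 genes. Of genes changed 1.75-fold, 2-fold and 4-fold it called 100%, of those changed 1.25-fold 0%, and of unchanged genes 0. Of 200 lists with no change, 8 lay apart. The simulated genes varied independently, so this does not cover lists whose genes move together. The alternatives covered the filter on low values, the probe set kept per gene, the fold limit, the variance model, the arrays in the fit, normalization, the replicate number as a block, 1 mean per pool, and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9.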

Results

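Kidney gene expression was compared between 4 rat strains at 30 days of age on Affymetrix rat expression arrays. SD is the outbred Sprague Dawley stock. PCK is a strain derived from it that carries a mutation of Pkhd1, the gene of autosomal recessive polycystic kidney disease. FHH is the inbred Fawn Hooded Hypertensive strain, and FHH.Pkhd1 is a congenic strain with a PCK segment of chromosome 9, where Pkhd1 lies, on the FHH background. The series title contrasts strains susceptible and resistant to polycystic kidney disease. For each strain, RNA from both kidneys of 6 animals was pooled and hybridized to 3 arrays, giving 12 arrays. The arrays of a strain were therefore technical replicates of 1 pool. All standard errors (SE), standard deviations and p-values given here set a difference between pools against the spread between arrays, and they carry no information on the spread between animals.

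Expression values were log2 signals, with array medians of 6.41 to 6.46. Correlations between arrays of the same pool were 0.9973 to 0.9985, and those between pools were 0.9862 to 0.996. The number of arrays limits the precision of the values. A gene was called when its limma adjusted p was under 0.05 and its difference reached 1.5-fold, among 10895 genes tested. No probe set was named for Pkhd1 in the annotation used, which names no gene for 9780 probe sets, so no value is given here for the gene at the congenic locus. Of the sex-linked genes, the Y-linked Eif2s3y was at 9.51 to 9.85 in the 4 pools, and every probe set of Xist, the X inactivation transcript, stayed below the detection level of 5.74. Where a gene's signal in a pool lay below that level, its log2 difference is given without a fold. The level is the 40th percentile of all values and not a measured background, so a signal below it may still be real.

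Control probe sets differed between pools as well. Poly-A spike-ins, added to RNA before labelling, differed by 0.36 in PCK minus SD, -1.10 in FHH.Pkhd1 minus FHH, 0.82 in PCK minus FHH.Pkhd1 and -0.64 in SD minus FHH. The 3' minus 5' difference of beta-actin, a measure of RNA integrity and labelling, differed by 0.23, -0.19, 0.13 and -0.28 in the same order. Each of these had a two-sided exact permutation p = 0.1, the smallest that 3 arrays against 3 allow.

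The comparison of PCK with SD asks how the kidney of the Pkhd1 mutant strain differs from that of the stock it came from. PCK and SD may also differ at other loci, and the comparison cannot separate these from the Pkhd1 mutation. Serpina3n, a secreted protease inhibitor, was higher in PCK (log2 difference 4.78 ± 0.08, SE, limma adjusted p = 5.45e-13), with its signal of 4.22 in SD below the detection level. Havcr1, which encodes kidney injury molecule 1, was 8.9-fold higher, at 9.25 ± 0.10 in PCK against 6.10 ± 0.04 in SD (log2, standard deviation, n = 3 arrays of 1 pool, limma adjusted p = 8.75e-11). The urea cycle enzyme Cps1 rose by 2.75 ± 0.13, and Gc, the vitamin D binding protein, was 7.06-fold lower in PCK (-2.82 ± 0.07, limma adjusted p = 5.18e-11).

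In all, 339 genes were called, 184 higher and 155 lower in PCK. Fam111a, a protease linked to host restriction of viruses, was 32.1-fold higher (5.00 ± 0.03). Other large increases were those of the aldo-keto reductase Akr1b8 (2.47 ± 0.09), the phosphatase Dusp15 (2.31 ± 0.11), the hemidesmosome collagen Col17a1 (2.05 ± 0.08), the amino acid transporter Slc7a12 (1.86 ± 0.04) and Pamr1 (1.86 ± 0.05). Large decreases were those of the choline phosphodiesterase Enpp6 (-2.73 ± 0.09), the soluble epoxide hydrolase Ephx2 (-2.60 ± 0.04), the protocadherin Pcdh9 (-2.57 ± 0.08), the kallikrein Klk1c4 (-2.53 ± 0.08) and Alb, albumin (-2.05 ± 0.05). Dusp15 (4.92) and Col17a1 (5.04) were below the detection level in SD, and Pcdh9 (4.72) in PCK. The other detected probe sets of Alb and Pcdh9 gave -0.72 and -1.04. RT1-Bb, a class II histocompatibility chain, gave 5.42 ± 0.08 from a signal of 4.39 in SD, below the detection level. A second detected probe set of RT1-Bb gave -5.19, and with the mean of its probe sets the gene was not called (0.12).

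Of the 22 measured tubule injury and repair genes, 4 rose and 1, Tff3, fell in PCK (-0.62 ± 0.04). Besides Havcr1, the chaperone clusterin, Clu, rose by 1.55 ± 0.05, and Gpnmb by 1.27 ± 0.06. The list's median was 0.35, above all 10000 random lists matched on expression, with camera adjusted p = 0.16 with an estimated correlation. Urothelial markers moved as far, with a median of 0.35 at the 99.95th percentile, none of 6 called, and Upk1b (0.58 ± 0.07) and Upk3a (0.52 ± 0.06) largest (adjusted p = 0.155 with an estimated correlation). Complement genes had a median of 0.24, and 2 of 12 rose, the C1 inhibitor Serping1 (1.34 ± 0.05) and the regulator Cfi (0.90 ± 0.07). Their median was also above all random lists (adjusted p = 0.203 with an estimated correlation). The antigen presentation list had a median of -0.05 and a mean of 0.22, which RT1-Bb raised. Members of the extracellular matrix list went both ways, with Lox at 1.06 ± 0.05 and Lum at -0.84 ± 0.07 among 2 higher and 1 lower of 30, and another probe set of Lox gave 0.48. Cfi was below the detection level in SD (5.70) and Lum in PCK (5.46).

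Cell cycle genes had a median of -0.19, below all random lists, but none of the 29 was called (limma, 1.5-fold). The largest differences were those of Ccnb2 (-0.49 ± 0.07) and Mki67 (-0.48 ± 0.07), and the list had adjusted p = 0.155 with an estimated correlation. In sterol synthesis, 3 of 16 genes fell and 1 rose, with a median of -0.25 below all random lists (adjusted p = 0.155 with an estimated correlation). The isomerase Idi1 stood at -1.20 ± 0.05 and lanosterol synthase, Lss, at -0.87 ± 0.03, or -0.46 by another probe set. The desaturase Sc5d was higher (1.17 ± 0.07), a call lost with the mean of its probe sets (0.32). Among 20 cAMP signalling genes, Creb1 (-1.13 ± 0.10) and the vasopressin receptor Avpr1a (-0.72 ± 0.10) fell, and the list's median of 0.02 lay at the 63.4th percentile. The growth factor Areg, of the EGF receptor axis, fell by 1.27 ± 0.07, and Axin2, a Wnt target, rose by 0.81 ± 0.10. Below the detection level were Avpr1a (5.32) and Areg (4.63) in PCK and Axin2 (5.00) in SD. The 23 cystic disease and cilium genes had a median of 0.01 with 1 called, Bbs1 (-0.61 ± 0.07), which was not called without PCK replicate 1 (-0.54) or with the mean of its probe sets (-0.55).

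The 10 intercalated cell markers were all positive, with a median of 0.24 and Foxi1 at 0.63 ± 0.05 (99.99th percentile, adjusted p = 0.0606 with an estimated correlation). Principal cell markers had a median of 0.15, with the water channel Aqp3 called at 0.63 ± 0.04 (99.83rd percentile, adjusted p = 0.155 with an estimated correlation). The 29 proximal tubule markers had a median of -0.04, at the 23rd percentile. All 3 measured red cell markers fell, with Ahsp, which fell below the detection level (5.72), at -1.91 ± 0.07, Alas2 at -1.13 ± 0.07 and Hbb at -0.79 ± 0.04 (list adjusted p = 0.0606 with an estimated correlation). In all, 14 of 31 lists lay outside the central 95% of random lists, where 1.55 would be expected if the genes of a list varied independently. Of all 31 lists, camera called 13 at a preset correlation and fry 22. The lowest adjusted p that camera gave with an estimated correlation was 0.0606. The counts of members adjusted over the list alone were the same as those over all genes tested, for every list and comparison.

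**Figure D1:**
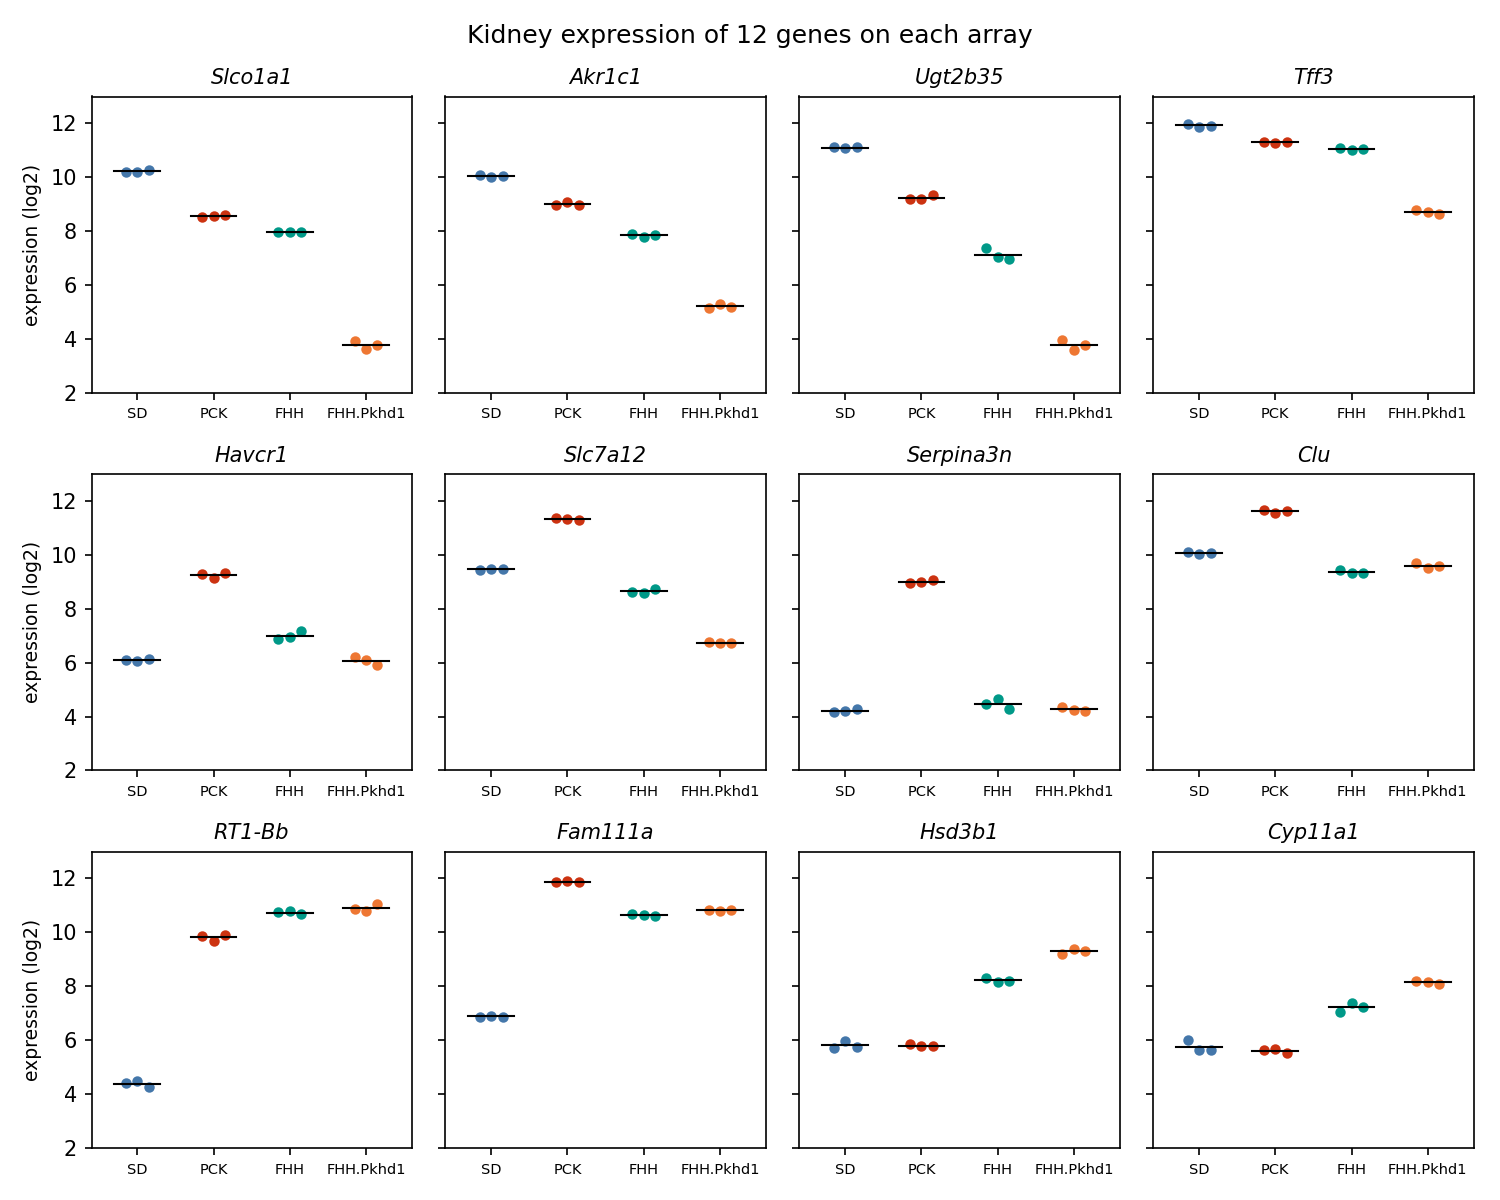
Expression of 12 genes on each of the 12 arrays, on a log2 axis, with the 4 strains side by side; each point is 1 array and each line the mean of the 3 arrays of a pool. Slco1a1 fell from 10.23 in SD to 8.57 in PCK and from 7.97 in FHH to 3.78 in FHH.Pkhd1, whereas Havcr1 was highest in PCK at 9.25 and at 6.07 in FHH.Pkhd1.

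The comparison of FHH.Pkhd1 with FHH asks what the PCK segment of chromosome 9 changes on the FHH background. Slco1a1, an organic anion transporter, fell below the detection level (-4.19 ± 0.06, SE), at 3.78 ± 0.15 in FHH.Pkhd1 against 7.97 ± 0.01 in FHH (log2, standard deviation, n = 3 arrays of 1 pool, limma adjusted p = 4.57e-13). The glucuronosyltransferase Ugt2b35 also fell below it, to 3.78 (-3.34 ± 0.10). The fatty acid hydroxylase Cyp4a8, still detected at 7.81, was 10.1-fold lower (-3.33 ± 0.05). The injury marker Havcr1, higher in PCK than in SD, was lower in FHH.Pkhd1 than in FHH (-0.93 ± 0.08, limma adjusted p = 1.03e-05).

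The segment went with 138 called genes, 43 higher and 95 lower. Among the lower were the aldo-keto reductases Akr1c13 (-2.93 ± 0.06), Akr1c1 (-2.64 ± 0.04) and AKR1C3l1 (-1.90 ± 0.05), while Akr1b7, of the same superfamily, rose. Also lower were the dehydrogenase Dhrs7l1 (-3.43 ± 0.07), the trefoil peptide Tff3 (-2.34 ± 0.04), Slc7a12 (-1.91 ± 0.04) and the protease inhibitor Pzp (-1.85 ± 0.05). Dhrs7l1 (4.67) and Akr1c1 (5.22) were below the detection level in FHH.Pkhd1. Of the 24 other detected probe sets of genes called lower, 21 had the same sign and 8 also fell by 1.5-fold. Higher in FHH.Pkhd1 were Akr1b7, which is abundant in the adrenal cortex (1.81 ± 0.05), the stearoyl-CoA desaturase Scd (1.53 ± 0.16), the neutrophil protein S100a9 (1.24 ± 0.08), Lsm14b (1.14 ± 0.10), the co-chaperone Dnajc7 (1.10 ± 0.06) and the acyl-CoA dehydrogenase Acadsb (1.03 ± 0.18). S100a9 (4.58), Lsm14b (5.13), Acadsb (5.20) and Akr1b7 (5.73) were below the detection level in FHH. Rab5c, an endosomal GTPase, rose by 0.98 ± 0.04.

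Of 5 measured adrenal markers 3 rose in FHH.Pkhd1, the steroidogenic genes Hsd3b1 (1.07 ± 0.07), Cyp11a1 (0.92 ± 0.10) and Star (0.83 ± 0.07), and the list's median of 0.83 was above all random lists (adjusted p = 0.0695 with an estimated correlation). Adipocyte markers had a median of 0.13 with none of 11 called higher (99.59th percentile, adjusted p = 0.822 with an estimated correlation). Ucp1 was called lower (-0.59), but not without FHH replicate 1 (-0.53) or FHH.Pkhd1 replicates 2 (-0.58) and 3 (-0.55). A second fat list, with no member called, had a median of 0.20 at the 100th percentile. Smooth muscle markers had a median of 0.17 with none of 9 called (99.82nd percentile, adjusted p = 0.258 with an estimated correlation). The urothelial and red cell lists did not lie apart, with medians of -0.11 and 0.08. The poly-A spike-ins were at 10.04 ± 0.11 in FHH.Pkhd1 against 11.14 ± 0.02 in FHH (log2, standard deviation, n = 3 arrays of 1 pool, two-sided exact permutation p = 0.1, the smallest the design allows).

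The injury and repair list had a median of -0.01 in FHH.Pkhd1, at the 13th percentile, with 3 genes lower, Havcr1, Tff3 and Gdf15 (-0.61 ± 0.07, or -0.51 and not called without FHH replicate 1). Interferon response genes had a median of -0.22, below all random lists, with 1 of 20 called, and adjusted p = 0.0695 with an estimated correlation. The gene called was Igtp (-0.65 ± 0.05), which was not called with the mean of its probe sets (-0.36). Principal cell markers had a median of 0.23, above all random lists, with 1 of 15 called, the sodium channel subunit Scnn1a (0.85 ± 0.08, or 0.46 with the mean of its probe sets, no longer called). Their adjusted p was 0.0695 with an estimated correlation. Cell cycle genes had a median of 0.16, above all random lists, with none of 29 called and Mcm6 highest at 0.58 ± 0.09 (adjusted p = 0.121 with an estimated correlation). The extracellular matrix list also had a median of 0.16, above all random lists, with none of 30 called and adjusted p = 0.121 with an estimated correlation. The proximal tubule list had a median of -0.01 (4.01st percentile), with Slc22a7 lower (-0.72 ± 0.05). The von Willebrand factor gene Vwf fell by 0.89 ± 0.06, while the endothelial list's median was 0.07. Fatty acid oxidation genes had a median of 0.05 and a mean of -0.13, the mean lowered by Cyp4a8. In all, 16 of 31 lists lay outside the central 95% of random lists.

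Chromosome 9 held 8 of the called genes, 5.8% against 3.9% of the tested genes (Fisher's exact test across genes, adjusted p = 0.654). The largest of them were Tmem14a (-0.98 ± 0.04), Nif3l1 (-0.85 ± 0.07), Slc22a7 (-0.72 ± 0.05), Khsrp (0.69 ± 0.08) and the nucleoside transporter Slc29a1 (0.69 ± 0.05). Nif3l1 and Khsrp were not called with the mean of their probe sets (-0.50 and 0.33). No chromosome passed the threshold in the 5 comparisons (110 tests, lowest adjusted p = 0.0541, for chromosome 4 in SD minus FHH).

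Genes called in both Pkhd1 comparisons were then set side by side, since PCK minus SD and FHH.Pkhd1 minus FHH share no array. Lower in both were 13 genes, against 1.35 expected for independent lists (Fisher's exact test across genes, adjusted p = 3.01e-09). They included Slco1a1 (-1.65 ± 0.06 in PCK), Ugt2b35 (-1.86 ± 0.10), Dhrs7l1 (-0.82 ± 0.07), Akr1c1 (-1.05 ± 0.04), Akr1c13 (-0.83 ± 0.06), Pcdh9, the purine receptor P2ry1 (-1.09 ± 0.11) and the channel Trpv1 (-0.84 ± 0.07). The Trpv1 call in PCK was lost with the mean of its probe sets (-0.50). Higher in both were Fgb, a fibrinogen chain (0.99 ± 0.06 in PCK and 0.69 ± 0.06 in FHH.Pkhd1), and Lsm14b, 2 genes against 0.73 expected (adjusted p = 0.164). P2ry1 was below the detection level in PCK, SD and FHH.Pkhd1, and Lsm14b in PCK, SD and FHH.

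Calls in opposite directions were also more frequent than expected. The odds ratio was 11.64 for genes lower in PCK and higher in FHH.Pkhd1, 5.549 for the reverse and 11.89 for genes lower in both. The excess of genes lower in both therefore does not by itself show a shared effect of the segment. Higher in PCK and lower in FHH.Pkhd1 were 8 genes against 1.6 expected (adjusted p = 0.000263), Havcr1, Slc7a12, Slpi, Azgp1, Eci2, Rarres1, Slc22a7 and Vwf. Lower in PCK and higher in FHH.Pkhd1 were 6 genes against 0.61 expected (adjusted p = 5.94e-05), Scd, Acadsb, Car3, Cyp26b1, Fcgr3a and Pou2f1. Acadsb was below the detection level in PCK, SD and FHH, Azgp1 in FHH.Pkhd1 and Fcgr3a in FHH. Another detected probe set of Cyp26b1 moved by -0.13 in PCK minus SD and 0.27 in FHH.Pkhd1 minus FHH, so its calls rest on 1 probe set. Across all tested genes, which are not independent replicates, the differences correlated with r = 0.056 and rho = 0.035. A fit with additive terms treats PCK and SD as 1 background, though they may differ at loci outside the segment. With 1 mean per pool and additive terms for background and Pkhd1 segment, which leaves 1 residual degree of freedom, limma called 0 genes for the segment, with 494 at unadjusted p under 0.05 where 545 would be expected by chance.

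**Figure D2:**
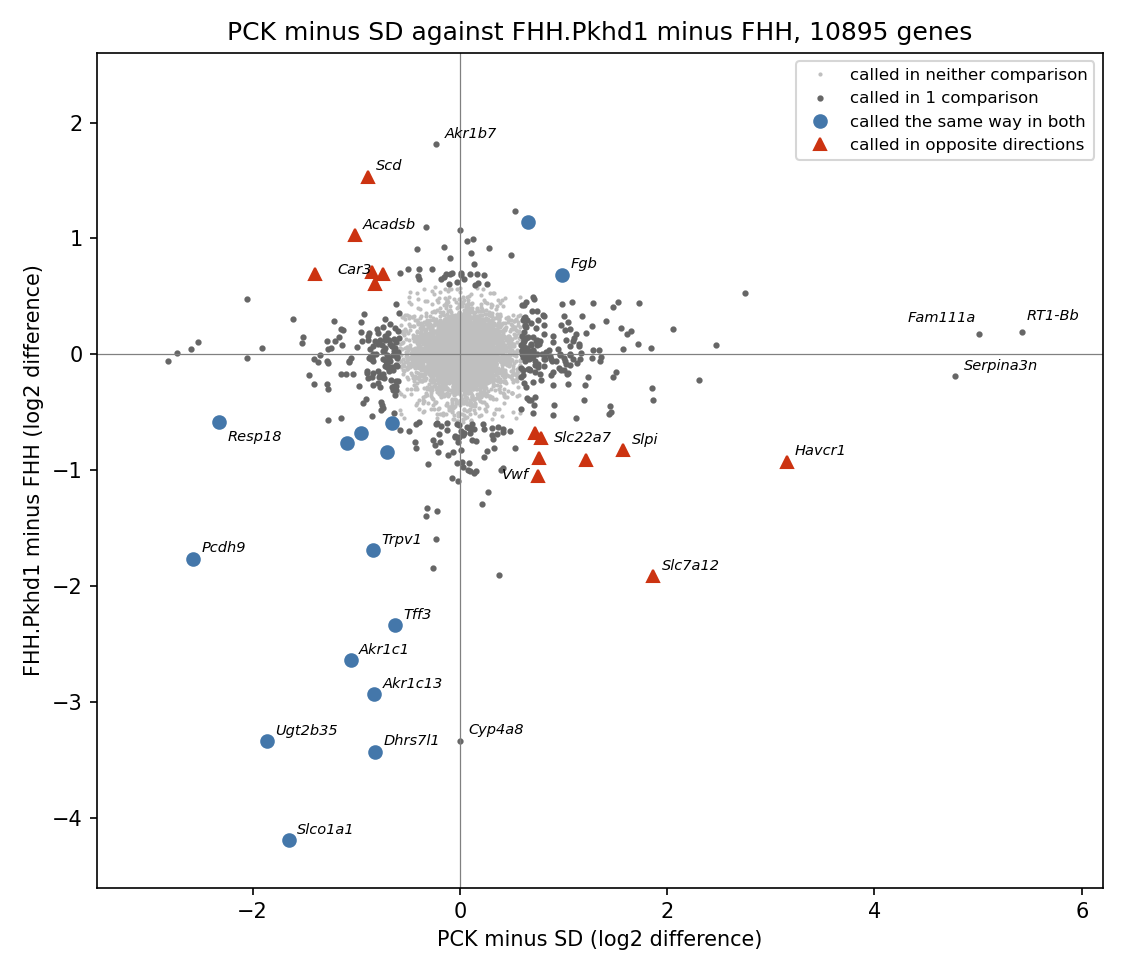
Log2 differences of 10895 genes in PCK minus SD (horizontal) and FHH.Pkhd1 minus FHH (vertical); circles are the 15 genes called the same way in both, triangles the 14 called in opposite directions, and grey dots the rest. The circles lie mostly at the lower left, with Slco1a1 at -1.65 and -4.19, and Havcr1 lies at the lower right at 3.15 and -0.93.

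PCK and FHH.Pkhd1 carry the same Pkhd1 segment on different backgrounds, and their comparison asks how the background sets expression in its presence. Ugt2b35 (5.46 ± 0.10, SE, limma adjusted p = 6.51e-13) and Slco1a1 (4.79 ± 0.06) were higher in PCK, with signals of 3.78 in FHH.Pkhd1, below the detection level. Slc7a12, detected in both pools, was 24.1-fold higher. Alb was lower in PCK (-4.22 ± 0.05, limma adjusted p = 1.71e-14, or -2.69 by its other detected probe set) and Scd 15.6-fold lower (-3.96 ± 0.16).

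Here 635 genes were called, 319 higher and 316 lower in PCK. Among the higher were Dhrs7l1 (4.89 ± 0.07), Serpina3n (4.72 ± 0.08), Cyp4a8 (4.46 ± 0.05), the acetyltransferase Nat8b (4.15 ± 0.04), Cps1 (4.10 ± 0.13), Akr1c13 (3.97 ± 0.06) and Akr1c1 (3.79 ± 0.04). Among the lower were Ephx2 (-3.83 ± 0.04), Akr1b7 (-3.69 ± 0.05), the crystallin Cryga (-3.36 ± 0.06), the lipogenic gene Thrsp (-2.63 ± 0.08), Pcdh9 (-2.42 ± 0.08) and Resp18 (-2.36 ± 0.06). Below the detection level were Dhrs7l1, Serpina3n, Cps1 and Akr1c1 in FHH.Pkhd1 (4.28 to 5.22) and Akr1b7, Pcdh9 and Resp18 in PCK (3.85 to 5.14). Other probe sets of Cps1 and Pcdh9 gave 2.36 and -0.88.

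Tubule injury and repair genes stood higher in PCK, with 8 of 22 called higher, a median of 0.36 above all random lists, and adjusted p = 0.214 with an estimated correlation. They included Havcr1 (3.18 ± 0.08), Tff3 (2.58 ± 0.04), Clu (2.03 ± 0.05) and the lipocalin Lcn2 (1.06 ± 0.04). Extracellular matrix genes went the other way, with 7 of 30 called lower, among them Lum (-2.15 ± 0.07), Postn (-1.35 ± 0.06) and Dcn (-0.76 ± 0.04), with Lum (5.46) and Postn (5.42) below the detection level in PCK. Their median of -0.22 was below all random lists (adjusted p = 0.388 with an estimated correlation). Cell cycle genes had a median of -0.44, with 6 of 29 called lower and none higher, led by the replication helicase subunits Mcm6 (-1.19 ± 0.09), Mcm4 (-0.83 ± 0.06) and Mcm2 (-0.78 ± 0.04). The cell cycle list lay below all random lists (adjusted p = 0.214 with an estimated correlation).

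Of 20 antigen presentation genes 8 were lower in PCK, among them the class II chains RT1-Da (-1.16 ± 0.04) and RT1-Db1 (-1.02 ± 0.06), and the median of -0.25 lay at the 0.02nd percentile (adjusted p = 0.338 with an estimated correlation). The calls of RT1-Ba (-1.25 ± 0.05) and RT1-Bb (-1.11 ± 0.08) were lost with the mean of their probe sets (-0.17 and -0.47). Interferon response genes had a median of 0.23, above all random lists, with 3 of 20 higher, Igtp at 0.93 ± 0.05 and Rig1 at 0.73 ± 0.03 (adjusted p = 0.214 with an estimated correlation). Macrophage markers had a median of 0.20, with 2 of 18 higher, Cd53 at 0.75 ± 0.05 and Ctss at 0.66 ± 0.04 (99.99th percentile, adjusted p = 0.214 with an estimated correlation). In the renin-angiotensin list, Agtrap (1.31 ± 0.04), Agt (1.13 ± 0.07) and Ace (1.09 ± 0.11) were higher and Agtr1b (-0.68 ± 0.07) was lower in PCK, with a median of 0.02 at the 81.8th percentile. Ace was below the detection level in FHH.Pkhd1 (5.63).

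Adrenal markers had a median of -2.04 in PCK minus FHH.Pkhd1, with 4 of 5 called lower, among them Hsd3b1 (-3.49 ± 0.07), Cyp11a1 (-2.54 ± 0.10) and Star (-2.04 ± 0.07), and adjusted p = 0.214 with an estimated correlation. Cyp11a1 (5.61) and Star (5.50) were below the detection level in PCK. Adipocyte markers had a median of -0.52, with 5 of 11 called lower, among them Fabp4 (-1.45 ± 0.06), Ucp1 (-1.13 ± 0.06) and Cidea (-1.13 ± 0.05), and adjusted p = 0.218 with an estimated correlation, while Cidec was positive (0.58, not called). Smooth muscle markers had a median of -0.28 and 2 of 9 called lower (0.51st percentile, adjusted p = 0.292 with an estimated correlation). Urothelial markers did not lie apart, with a median of 0.01 and none of 6 called. In all, 14 of 31 lists lay outside the central 95% of random lists.

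SD and FHH do not carry the segment, and their comparison asks how the pools of the background strains differ. Ugt2b35 was 15.8-fold higher in SD (3.98 ± 0.10, SE, limma adjusted p = 5.01e-11), Nat8b 15.3-fold higher (3.94 ± 0.04) and Gc 9.41-fold higher (3.23 ± 0.07). Fam111a was 13.6-fold lower in SD (-3.76 ± 0.03, limma adjusted p = 9.01e-16) and Cryga 13.5-fold lower (-3.75 ± 0.06).

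The comparison of SD with FHH gave 361 called genes, 170 higher and 191 lower in SD. Also higher in SD were Dhrs7l1 (2.28 ± 0.07), Slco1a1 (2.26 ± 0.06), Akr1c1 (2.21 ± 0.04), the alpha globin Hba-a3 (2.07 ± 0.08), antithrombin, Serpinc1 (1.93 ± 0.04), and Cps1 (1.88 ± 0.13), which was below the detection level in FHH (4.16) and stood at 0.47 by another probe set. Also lower in SD were Hrg (-1.91 ± 0.06), Apoc2 (-1.90 ± 0.05), Akr1b8 (-1.89 ± 0.09), Mis18a (-1.89 ± 0.07), Arxes1 (-1.88 ± 0.07) and the cytochrome oxidase subunit Cox8b (-1.89 ± 0.11). The matrix genes Tnc (-1.21 ± 0.04) and Postn (-1.17 ± 0.06) were among 4 of 30 called lower, with 1 higher and a list median of 0.00. Mis18a (5.54) and Postn (5.42) were below the detection level in SD.

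RT1-Bb read -6.34 ± 0.08 in SD minus FHH, but its other probe set gave 5.23 and the mean of both gave -0.56, which was not called. RT1-Ba changed direction between -0.72 ± 0.05 and 0.99 with the mean of its probe sets. RT1-Bb and RT1-Ba were among the 5 of 20 antigen presentation genes called lower in SD, as were the class II gene RT1-DMb (-0.75 ± 0.04) and the class I gene RT1-CE16 (-0.98 ± 0.11), while Cd74 stood at -0.01 ± 0.03. The list's median of -0.19 lay at the 0.05th percentile (adjusted p = 0.41 with an estimated correlation).

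Red cell markers were all higher in SD, Ahsp by 1.40 ± 0.07, Alas2 by 1.21 ± 0.07 and Hbb by 0.90 ± 0.04, and camera called this list alone in the 5 comparisons with an estimated correlation (adjusted p = 0.0359). Adipocyte markers were lower in SD, with 6 of 11 called and a median of -0.59, among them Cidea (-1.70 ± 0.05), Lpl (-1.48 ± 0.04) and the brown fat gene Ucp1 (-1.31 ± 0.06). That list lay below all random lists (adjusted p = 0.0759 with an estimated correlation). Adrenal markers had a median of -1.11, with Hsd3b1 (-2.42 ± 0.07), Cyp11a1 (-1.46 ± 0.10) and Star (-1.11 ± 0.07) called of 5 (adjusted p = 0.0759 with an estimated correlation). Star was below the detection level in SD (5.60). Antioxidant and glutathione genes had a median of 0.27, above all random lists, with 5 of 19 higher and 1 lower, led in size by Gsta3 (-0.99 ± 0.06) and Gstm1 (0.78 ± 0.05), and adjusted p = 0.0745 with an estimated correlation. Cell cycle genes had a median of -0.01 with none of 29 called. In all, 10 of 31 lists lay outside the central 95% of random lists.

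**Figure D3:**
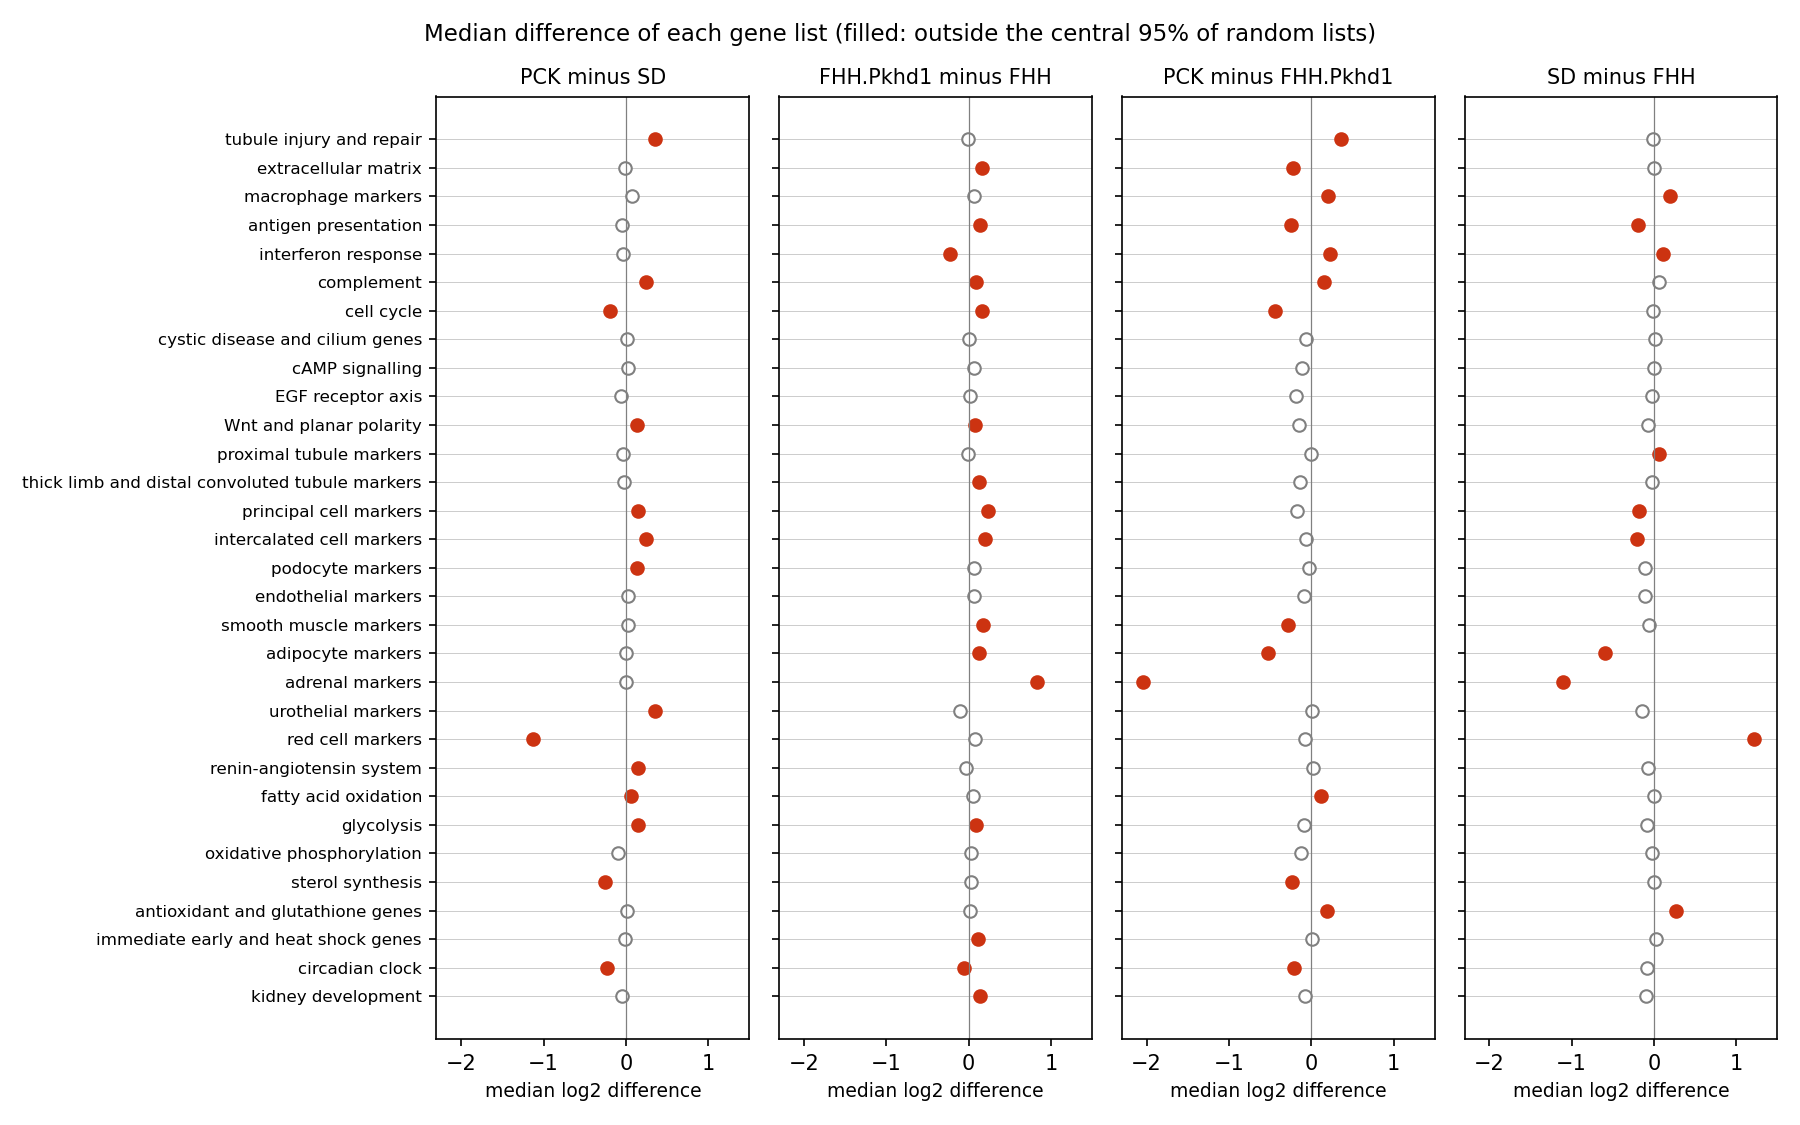
Median log2 difference of 31 gene lists in 4 comparisons; filled points lie outside the central 95% of 10000 random lists matched on expression, open points inside it. Adrenal markers reached -2.04 in PCK minus FHH.Pkhd1 and 0.83 in FHH.Pkhd1 minus FHH, and tubule injury and repair genes 0.35 in PCK minus SD against -0.01 in FHH.Pkhd1 minus FHH.

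The interaction tests whether the difference of PCK from SD equals that of FHH.Pkhd1 from FHH. By that test 547 genes were called at the 1.5-fold limit, 316 of them with a larger value in the first comparison and 231 with a smaller. Tubule injury genes had a larger value in the first, with Havcr1 at 4.08 ± 0.12 (SE, limma adjusted p = 3.39e-10), Tff3 at 1.71 ± 0.06 and Clu at 1.33 ± 0.07 among 6 of 22 called, all positive. Tff3 was lower in both comparisons, and its positive value came from the larger fall in FHH.Pkhd1 (-2.34 against -0.62 in PCK). Serpina3n, detected in PCK alone, stood at 4.96 ± 0.11 and Fam111a at 4.83 ± 0.04. At the negative end were Gc (-2.76 ± 0.10), Enpp6 (-2.74 ± 0.13), Ephx2 (-2.65 ± 0.06) and Klk1c4 (-2.64 ± 0.11).

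The injury list had a median interaction of 0.37, above all random lists (adjusted p = 0.173 with an estimated correlation). Urothelial markers had a median of 0.42 at the 99.91st percentile, with 3 of 6 called (adjusted p = 0.145 with an estimated correlation). These were Upk1b (0.78 ± 0.10), Upk1a (0.60 ± 0.08) and Upk3a (0.60 ± 0.08), of which Upk1a was not called without PCK replicates 2 (0.58) or 3 (0.55), FHH replicate 2 (0.56) or FHH.Pkhd1 replicate 1 (0.58), and Upk3a not without PCK replicate 1 (0.56) or SD replicates 2 (0.58) or 3 (0.55). The cell cycle list had a median of -0.42, below all random lists, with 4 of 29 called, among them Mcm6 (-0.82 ± 0.12), Cdk1 (-0.78 ± 0.07) and Mki67 (-0.73 ± 0.10), and adjusted p = 0.114 with an estimated correlation. Sterol synthesis genes had a median of -0.28, with 4 of 16 called lower and 1 higher, led by Idi1 at -1.31 ± 0.07 (adjusted p = 0.193 with an estimated correlation). Slco1a1 (2.54 ± 0.08), Dhrs7l1 (2.61 ± 0.11) and Cyp4a8 (3.33 ± 0.08) had positive interactions, since they fell further in FHH.Pkhd1 than in PCK, where Cyp4a8 did not differ from SD (0.00 ± 0.05). In all, 17 of 31 lists lay outside the central 95% of random lists.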

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

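The tests for female rats, for a lower share of proximal tubule and for 1 outside source were chosen after the results were seen, as were the use of binomial intervals in the tests of other probe sets and the count of each probe set once. So were the matching of the second fat list without synonyms and the limits on which genes are given with an interaction. The decision that splits of the arrays give no verdict on the interaction and on the shared genes was also made after their counts were seen.

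The difference of PCK from SD and that of FHH.Pkhd1 from FHH were unequal by at least 1.5-fold, by the interaction test in limma, for 547 genes. Among them, 8 genes were higher in PCK and lower in FHH.Pkhd1 than in the strain each was compared with: Havcr1 (interaction 4.08), Slc7a12 (3.78), Slpi (2.40), Azgp1 (2.12), Eci2 (1.80), Vwf (1.66), Slc22a7 (1.51) and Rarres1 (1.40). Another 6 went the other way: Scd (-2.42), the retinoic acid hydroxylase Cyp26b1 (-2.09, or -0.40 by its other detected probe set), Acadsb (-2.05), the Fc receptor Fcgr3a (-1.56), the carbonic anhydrase Car3 (-1.43) and Pou2f1 (-1.42). Further large positive interactions were those of RT1-Bb (5.23, or 0.09 with the mean of its probe sets), Serpina3n (4.96), Fam111a (4.83), Cyp4a8 (3.33), Dhrs7l1 (2.61), Slco1a1 (2.54) and Dusp15 (2.53). Negative ones were those of Gc (-2.76), Enpp6 (-2.74), Ephx2 (-2.65), Klk1c4 (-2.64), Alb (-2.53, or -1.35 by its other detected probe set), Akr1b7 (-2.04) and RT1-T24-3 (-2.02). For Gc the SD pool stood apart, at 3.23 in SD minus FHH against 0.47 in PCK minus FHH.Pkhd1 and -0.06 in FHH.Pkhd1 minus FHH. Fam111a was likewise at -3.76, 1.07 and 0.17.

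Members of the gene lists with an interaction of at least 2-fold fell into several groups. Tubule injury genes were positive, with Tff3 at 1.71, Clu at 1.33 and Gpnmb at 1.30, and so were the median of the urothelial markers (0.42) and Upk1b (0.78). Unlike Clu and Gpnmb, Tff3 was not higher in PCK than in SD (-0.62) but fell further in FHH.Pkhd1 (-2.34). The complement genes Serping1 and Cfi stood at 1.30 and 1.16, and Cd53 at 1.06. RT1-CE16 stood at 1.41, while its antigen presentation list had a median of -0.14 and a mean of 0.12, with 3 members lower and 2 higher. Ace stood at 1.25 and Lpl at 1.03. Red cell genes were negative, with Ahsp at -1.96 and Alas2 at -1.21, as were Creb1 (-1.34), Jun (-1.32, or -0.33 by another probe set) and the steroidogenic genes Cyp11a1 (-1.08) and Hsd3b1 (-1.08). The red cell list set the SD pool apart, with medians of -1.13 in PCK minus SD and 1.21 in SD minus FHH. Its medians were 0.08 in FHH.Pkhd1 minus FHH and -0.08 in PCK minus FHH.Pkhd1. A further probe set of Jun moved with the main one in FHH.Pkhd1 minus FHH (0.94 against 0.91). Of the sterol genes, Idi1 stood at -1.31 and Sc5d at 1.16, or 0.31 with the mean of its probe sets.

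Other splits of the arrays were counted for these results. For each of the 4 pairwise comparisons 1 of the 10 splits of its 6 arrays, the real one, gave as many genes, and the splits are too few for a share under 0.05. The real counts were 339, 138, 635 and 361, and the highest other count was 0. For the interaction, 2 of 100 splits gave as many genes as the real 547. The highest other, 1332, came from a split that kept the 3 FHH arrays and the 3 FHH.Pkhd1 arrays together and mixed PCK with SD, so it followed the pools and points to a structure of the samples. For the 15 genes called the same way in both Pkhd1 comparisons, 1 of 100 splits, the real one, gave as many, and the highest other gave 0. The arrays are technical replicates of 4 pools, so the counts set differences between pools against array noise alone. They decide nothing about chance differences between animals.

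Probe sets outside the comparisons of the report also differed. Poly-A spike-ins were lower by 2.14-fold in FHH.Pkhd1 than in FHH (-1.10, two-sided exact permutation p = 0.1, the smallest possible). Hybridization spike-ins were lower too (-0.41, exact p = 0.1). Of 4691 detected probe sets without a single gene symbol, 225 were called in PCK minus SD, 106 in FHH.Pkhd1 minus FHH, 424 in PCK minus FHH.Pkhd1, 219 in SD minus FHH and 366 in the interaction.

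The first pattern weighed was the fall of Slco1a1, Ugt2b35, Akr1c1 and other genes in FHH.Pkhd1. Female rats in that pool are argued against by the Y-linked gene Eif2s3y, which differed by -0.06. A share of the whole proximal tubule lower by 1.5-fold or more is argued against by that list's median of -0.01 (95% interval -0.03 to 0.06, from resampling its 29 genes). The interval covers the spread between genes of these pools alone. The median lay at the 4.01st percentile of matched random lists, so a small fall of the share is not excluded. Members ran from -0.72 to 0.32, and a fall of 1 part of the tubule was not tested. Sequence variants under single probe sets stay open: Slco1a1, Ugt2b35 and Akr1c1 had no other detected probe set, and of 24 such probe sets of 16 other genes called lower 33.3% also fell by 1.5-fold (exact 95% interval 15.6 to 55.3 if probe sets are independent, bound 50), among them those of Cyp4a8 (-3.22), Trpv1 (-1.40) and Pcdh9 (-1.21). Over all called genes the share was 33% in PCK minus SD and 40% in SD minus FHH. In FHH.Pkhd1 minus FHH it was 39.5%, a share that includes the 24 probe sets of the genes called lower. By the other comparisons a low share is therefore not particular to the genes that fell. An effect of the chromosome 9 segment, of other loci that differ between the strains, or of the pools' animals may also explain the fall, and the design cannot separate them.

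The second pattern was the higher level of steroidogenic genes in FHH.Pkhd1 than in FHH, and of adipocyte genes in FHH than in SD, for which strain differences stay open, untested. Adrenal tissue in the pools is a candidate explanation: a second list of adrenal cortex genes stood at the 99.86th percentile in FHH.Pkhd1 minus FHH (median 0.21), though at the 52.99th in SD minus FHH, where Gata6 (0.28) and Soat1 (0.19) were higher in SD and Mgarp (-0.55), Prkar2b (-0.38) and Fdx1 (-0.15) lower. None of the 7 measured genes of that second list was called in FHH.Pkhd1 minus FHH. There 16 of 31 lists lay apart, 14 of them higher, so the 99.86th percentile does not by itself single out adrenal tissue. The excess over SD rose by 2.36 to 2.46 times for Hsd3b1, Cyp11a1 and Star. The highest over lowest ratio was 1.04, or 1.20 with the uncalled Cyp21a1, as 1 outside source or a coordinated strain difference would give. It was taken only for called markers and for uncalled ones whose signal in FHH exceeded that in SD beyond its error. Of the 5 tested markers, Th (5.66 in SD and 5.71 in FHH) had no such excess and was left out. Star itself was below the detection level in SD (5.60). Akr1b7, below that level in SD and FHH and not on the adrenal list, was given no ratio. It rose by 1.81, further than Hsd3b1 (1.07), so the shared ratio covers only the markers named with it. Among adrenal markers below the detection level, Pnmt (0.61 ± 0.12), Chgb (0.54 ± 0.13), Chga (0.53 ± 0.06) and Cyp11b1 (0.37 ± 0.11, reaching 3.94) had higher signals in FHH.Pkhd1, while Dbh (0.09 ± 0.08) and Nr5a1 (-0.09 ± 0.12) differed little. A second fat list stood at the 1.87th percentile in SD minus FHH (median -0.15), as fat tissue on the kidneys would give. In that comparison 10 of 31 lists lay apart, so the percentile does not by itself single out fat tissue. However, Pnpla3 (0.26) of that list and Cidec (0.22) and Lipe (0.21) of the first were higher in SD than in FHH. The second fat list stood at the 100th percentile in FHH.Pkhd1 minus FHH (0.20). There Ucp1 (-0.59), Cidec (-0.46), Adipoq (-0.28), Angptl4 (-0.26), Aqp7 (-0.17) and Plin4 (-0.14) were lower, which fat tissue would not bring.

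The third pattern was the set of differences of at least 4-fold between pools. Sequence variants or transcript ends under single probe sets could produce them, and 87.5% of 16 values of other detected probe sets of 9 such genes moved the same way by at least 1.5-fold. The values came from 10 probe sets, some seen in several comparisons, and with each counted once 9 did so (90%), with an exact 95% interval of 55.5 to 99.7 that crosses the bound of 75, so the explanation stays open. The exceptions were values of RT1-Bb, whose probe sets moved in opposite directions in PCK minus SD (5.42 and -5.19), and a sequence difference between class II alleles is a candidate explanation there.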

How the results depend on the processing

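The alternatives given here were chosen before the results were seen. With a limit of at least 2-fold, the counts of called genes were 111 (PCK minus SD), 31 (FHH.Pkhd1 minus FHH), 201 (PCK minus FHH.Pkhd1), 114 (SD minus FHH) and 170 (interaction), with 4 shared in direction by both Pkhd1 comparisons. With no fold limit they were 3934, 2423, 5877, 4041 and 3345, with 648 shared. Both follow from the limit itself. Lists called by camera with an estimated correlation numbered 0, 0, 0, 1 and 0 in that order, and camera with a preset correlation called 10 in the interaction. Fry called 22 in PCK minus SD, 26 in PCK minus FHH.Pkhd1 and 20 in SD minus FHH. With 1 mean per pool, limma called 0 genes for the Pkhd1 term, 494 at unadjusted p under 0.05, with 1 residual degree of freedom.

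Leaving out each array in turn gave 338 to 359, 132 to 148, 618 to 649, 355 to 372 and 532 to 567 called genes, 15 to 17 shared genes, 14 to 16, 12 to 16, 13 to 17, 10 to 13 and 13 to 18 lists apart, and 5 to 6.5% of called genes on chromosome 9. It ended 2 to 9 of 333 named calls (of 330 without PCK replicate 3). The mean of a gene's probe sets ended 34 of 324 and reversed RT1-Ba in SD minus FHH to 0.99, where its probe sets differ in sign. Other settings of filter, variance model, arrays and normalization ended 0 to 7.

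The replicate block ended 0 of 333 named calls, with Slco1a1 at -4.19 in FHH.Pkhd1 minus FHH under it. Arrays with the same number share only a number: their deviations correlated between -0.33 and 0.34 (mean -0.01, 18 pairs). Genes with signals below the detection level of 5.74 in all pools were not tested.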

Other observations

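The change to matching gene names without regard to case in the test of neighbouring genes was made after its first result was seen, and the count with gene families kept was added after it.

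Circadian clock genes differed between pools, and the labels give no time of day. In PCK minus SD, Npas2 (0.81) and Bmal1 (0.70) were higher and their repressors Bhlhe40 (-0.73) and Bhlhe41 (-0.70) lower, with a list median of -0.23 below all 10000 random lists (adjusted p = 0.274 with an estimated correlation). In PCK minus FHH.Pkhd1, Bhlhe40 stood at -1.44 and Dbp at -0.91. Agtrap, a binding partner of the angiotensin receptor, was higher in SD than in FHH (1.45).

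A run of called genes around Pkhd1 was proposed for FHH.Pkhd1 minus FHH, because the congenic segment replaces that part of chromosome 9. Among the 60 tested genes nearest to Pkhd1 in GRCr8 order, 5 were called: Tmem14a, Slc22a7, Slc29a1, Adgrf1 and Gsta1, the last 2 named after their values were seen. Random sets of tested genes held 0.76 on average, and the window stood at the 99.96th percentile. These sets were drawn from all chromosomes and not as runs of neighbours, so the percentile does not allow for neighbours that move together. Tmem14a, Slc29a1 and Gsta1 moved toward the PCK level. Slc22a7 (FHH 8.60, FHH.Pkhd1 7.87, PCK 8.93) and Adgrf1 (6.14, 5.49 and 7.31) moved away from it. Adgrf1 was below the detection level in FHH.Pkhd1. PCK also differs from FHH.Pkhd1 in background, so its level does not show what a PCK allele does on FHH. The directions therefore cannot decide whether local effects of the segment explain the run. Chromosome 9 as a whole held 8 of the 138 called genes. Blocks of neighbouring genes across all chromosomes stay open, with 1 neighbouring pair called the same way against a mean of 0.94 in shuffled orders (57.1th percentile), pairs with a shared symbol start left out. With those pairs kept there were 4 against a mean of 0.98 (99.04th percentile), the others being Ugt2b35 with Ugt2b7, Akr1c1 with AKR1C3l1, and AKR1C3l1 with Akr1c13, whose related sequences may also share signal.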
